A study of Mus musculus with 18 samples.

How the data were processed

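RNA was taken with Trizol and a column step with DNase from KPCA.B cells, and polyadenylated RNA was made into libraries with the NEBNext Ultra II kit, per the labels' protocols. Before that the cells were grown in conditioned medium mixed 1:1 with fresh high-glucose DMEM with 4% serum, EGF at 2 ng/mL and an insulin, transferrin and selenium supplement. The 18 libraries fell into 6 groups of 3 by hairpin (shControl, shNdufa5_1, shNdufa5_2) and medium (PCM, SCM), taken from the labels. All 18 columns of the table were matched to a library by name.

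The authors deposited a table of FPKM values (fragments per kilobase of gene and per megafragment of the library) for 54532 Ensembl mouse genes with their names. STAR 2.6.1, DESeq2 and the mouse builds GRCm38 and mm10 are named in the submitters' processing notes. The counter, the gene lengths and the denominator of the FPKM values are not given in the sources used here, and neither is whether fragments were counted by strand, so antisense genes and genes with near-identical copies are uncertain. Of the gene identifiers 99.8% were in the GENCODE annotation of GRCm38, which gave gene lengths and GC content for 54409 genes, and 25842 genes were above 0 in at least 1 library.

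Low FPKM values of a gene were whole multiples of a step, which gave the number of fragments. Among values of at most 20 fragments, 99.5 to 99.8% per library came out whole within 0.1 fragments for genes with a single transcript and 96.6 to 97.8% for other genes. The depth recovered in this way was 13.8 to 38.9 M (M, mega) fragments per library, while the denominators of the FPKM values were 12.94 to 35.15 M. Median-ratio factors over 12938 genes were 1.008 in every library, so the deposited values were already scaled to a common median gene, and FPKM sums ran from 290240 to 484520 per library. Between 10987 and 11239 genes per library had an FPKM above 1.

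Values were tested as log2(FPKM + 1), a scale that understates the change of low genes, with limma 3.58.1 in R 4.3.3, with the package data.table at version 1.17.8. A single model held 1 coefficient per group, with moderated variances that followed a trend with the mean and no replicate block. The filter kept the 11084 genes with a mean FPKM of at least 1 over the 18 libraries, which the fit uses without regard to group. Each of 10 contrasts was tested two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The contrasts were SCM against PCM in each genotype, each hairpin against shControl in each medium, the difference of each hairpin's response to SCM from that of shControl, and the same difference averaged over both hairpins. For Ndufa5 an exact permutation test of the FPKM values stood beside the limma result. Fold changes and p-values rest on 3 libraries per group.

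On simulated data made from these genes' means and spreads, with 200 of 11084 genes changed by a log2 of 0.5, the fit recovered 74% for SCM against PCM in shControl with 11 false calls and 61.5% for the averaged interaction with 4. At a log2 of 1 it recovered 96.5% with 11 false calls and 94% with 6. In shNdufa5_1, left unchanged in both simulations, SCM against PCM gave 1 and 0 false calls.

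The tests, the samples in each fit, the rule for named genes, the other settings to be tried and 32 gene lists with 791 members were fixed before the data were examined. The lists covered complex I subunits (without Ndufa5) and assembly factors, complexes II to V, the mitochondrial genome, glycolysis, the TCA cycle, ATF4 targets, ER stress, mitochondrial chaperones and proteases, the inflammatory secretome with NF-kB targets, interferon-stimulated genes, MHC class I antigen presentation, p53 targets, S phase, and G2 and M phase. Further lists held mesenchymal and epithelial genes, extracellular matrix, integrins and adhesion, targets of TGF-beta, of YAP and TEAD, of HIF and of NRF2, cholesterol synthesis, immediate early and growth factor response genes, stem cell-associated genes, replication-dependent histones, ribosomal proteins, and markers of fibroblasts, immune cells, endothelium and mesothelium. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, beside camera with an estimated correlation and beside fry. The 3 lists with fewer than 5 tested members are given as values only.

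Named genes followed a fixed rule. Ndufa5 came first in every library. For SCM against PCM in shControl, the change shared by both hairpins in PCM, that in SCM, and the averaged interaction, the rule took the 10 genes that rose most and the 10 that fell most among called genes whose groups of libraries did not overlap. A shared change had to be called the same way with both hairpins and was ranked by the smaller of the 2 absolute differences, and the interaction had to have the same sign for each hairpin. Genes with only a clone or model name were passed over. Within each list up to 4 called members with the largest absolute differences were taken, or up to 2 with the highest mean where none was called. Gm23935 lies outside the rule and was chosen after its values were seen.

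Other settings fixed at that point were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, no variance trend, a fit of only the groups compared, an absolute log2 difference of at least 1, a replicate block, leaving out each library in turn, an estimated correlation, and fry. After the data were seen, 4 more were added: scaling by library total, voom on the recovered fragments, only genes of at least 300 bp, and removal in each library of the smooth trend with GC content and length. Overlaps of comparisons that share control libraries were set beside 100 simulations of unchanged groups, and the covariances also with that trend removed. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A few genes that the rule took are not reported here. No sample was left out, and reads were not analysed here.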

Results

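Gene expression was measured by sequencing of polyadenylated RNA from KPCA.B, a mouse line of high-grade serous ovarian cancer. The cells carried a control short hairpin RNA (shControl) or a hairpin against Ndufa5 (shNdufa5_1 or shNdufa5_2), a gene for an accessory subunit of respiratory complex I, the NADH dehydrogenase of the mitochondrial inner membrane. They were grown in a 1:1 mix of fresh medium with medium conditioned by proliferating, vehicle-treated cells (PCM) or with medium conditioned by cells that cisplatin, a platinum drug that crosslinks DNA, had driven into senescence, a lasting arrest of division (SCM). Genotype and medium gave 6 groups of 3 libraries each, 18 libraries in all. The series asked what the secretome of senescent cells does to transcription in neighbouring cells and how Ndufa5 bears on it. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

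Depth was read from the steps of the low values and came to 15.3, 33.8 and 17.6 M fragments (M, mega) in the shControl libraries in PCM and to 15.2, 38.9 and 15.4 M in those in SCM. The shNdufa5_1 libraries held 16.4, 15.3 and 15.8 M in PCM and 17.0, 20.8 and 17.1 M in SCM. The libraries labelled shNdufa5_2 held 16.7, 16.8 and 13.8 M in PCM and 16.4, 19.3 and 13.8 M in SCM. Replicates of a group correlated at r of 0.979 to 0.99 across the 11084 genes tested.

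Ndufa5 fell in the shNdufa5_1 libraries and kept most of its level in those labelled shNdufa5_2. The gene (ENSMUSG00000023089) lies on the minus strand of chromosome 6 from 24518666 to 24528013 in GRCm38, with 1032 bp of exons. In PCM its FPKM was 15.2, 19.0 and 22.1 in the shControl libraries, 6.23, 6.39 and 6.85 in the shNdufa5_1 libraries and 18.7, 17.2 and 16.8 in the libraries labelled shNdufa5_2. In SCM it was 22.3, 26.2 and 20.9 in shControl, 6.46, 6.78 and 6.23 with shNdufa5_1 and 14.6, 16.1 and 20.2 in the libraries labelled shNdufa5_2. Group means with shNdufa5_1 were 34.6% of shControl in PCM (6.49 ± 0.324 against 18.8 ± 3.45, SD, n = 3 each) and 28% in SCM (6.49 ± 0.275 against 23.1 ± 2.77). In the libraries labelled shNdufa5_2 they were 93.4% (17.5 ± 1) and 73.4% (17.0 ± 2.91).

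The log2 difference of shNdufa5_1 from shControl was -1.39 in PCM (SE 0.12, limma adjusted p = 1.47e-07) and -1.68 in SCM (adjusted p = 9.8e-09). For the libraries labelled shNdufa5_2 it was -0.08 in PCM (95% interval -0.34 to 0.18, adjusted p = 0.647) and -0.43 in SCM (-0.69 to -0.17, adjusted p = 0.0125). Exact two-sided permutation tests gave p = 0.1, the smallest that 3 against 3 libraries allow, for shNdufa5_1 in both media and for the libraries labelled shNdufa5_2 in SCM, and p = 0.6 for the latter in PCM. With the trend of each library with GC content and length removed, the fall in SCM in the libraries labelled shNdufa5_2 was -0.31 (adjusted p = 0.0608), and it ranged from -0.56 without its replicate 3 to -0.33 without its replicate 1. The level of the target gene thus did not set the libraries labelled shNdufa5_2 apart from shControl in PCM, and every direction drawn from these libraries below carries that limit. The medium itself moved Ndufa5 by 0.30 in shControl (adjusted p = 0.0436, exact permutation p = 0.2), by 0 with shNdufa5_1 and by -0.05 in the libraries labelled shNdufa5_2, and the difference between the hairpins' and the control's responses did not pass (-0.32, adjusted p = 0.0975).

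**Figure D1:**
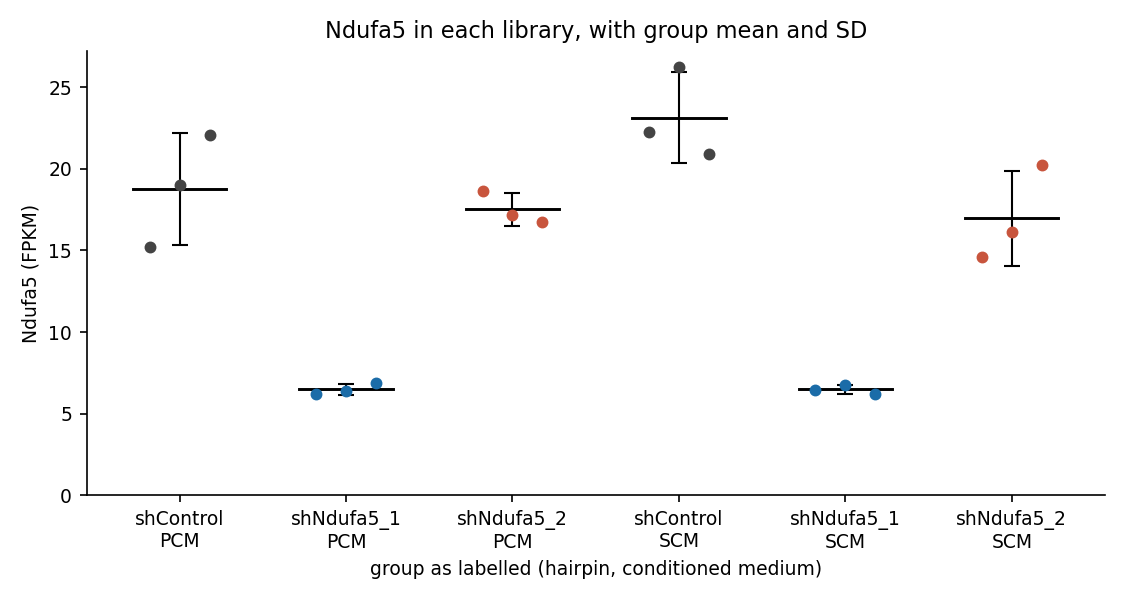
Ndufa5 level (FPKM, linear axis from 0) in each of the 18 libraries by genotype and medium, with points for libraries, lines for group means and error bars for the SD of 3 libraries. The shNdufa5_1 libraries lie between 6.23 and 6.85, below every other library, and those labelled shNdufa5_2 between 14.6 and 20.2.

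The first comparison asked what SCM did to cells with the control hairpin. Hspa1b, Lcn2, Hspb1 and Slpi were among the genes that rose most, and Btg2, Srsf3 and Gadd45g among those that fell most. Hspa1b, an inducible heat shock protein of the Hsp70 family, rose from 1.27 ± 0.303 to 19.8 ± 1.32 FPKM (SD, n = 3 each), a log2 difference of 3.20 ± 0.16 (SE). Fragments of its near-identical copy Hspa1a cannot be told from it with certainty. The small heat shock protein gene Hspb1 rose by 2.52 ± 0.19. Lcn2, whose product lipocalin-2 binds bacterial siderophores, rose from 5.54 ± 0.257 to 41.5 ± 1.37 FPKM (2.70 ± 0.08). Slpi, which encodes a secreted inhibitor of leukocyte proteases, rose by 2.45 ± 0.09. Irf7, a transcription factor of the interferon response, rose by 1.86 ± 0.10. Among the falls, Btg2, an antiproliferative target of p53, changed by -1.48 ± 0.15, the splicing factor gene Srsf3 by -1.44 ± 0.04 and the growth arrest gene Gadd45g by -1.38 ± 0.06. Csf2, the gene of the cytokine GM-CSF, changed by -1.22 ± 0.13 and Orc2, for a subunit of the origin recognition complex, by -1.20 ± 0.10. Prps1l3 and Filip1l fell by 1.32 and by 1.27.

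By limma with Benjamini-Hochberg adjustment, 6863 of 11084 genes changed between the media in shControl cells, 3517 up and 3346 down. Of these, 254 of the rises and 37 of the falls were at least 2-fold. The deposited values equalise the median gene between libraries. Scaled by library totals instead, the median of all genes moved by -0.20 and the calls split into 1937 up and 5413 down. The same rule named 8 features shorter than 300 bp with few fragments, so their values are uncertain. Of these, Mir669n (2.83), Mir194-1 (2.43), Mir6955 (2.42), Mir6960 (2.13) and Snord7 (2.05) rose, and mt-Tg (-2.75), Rnu73b (-1.98) and mt-Tq (-1.78) fell, each with at most 64 fragments in a library. Across genes the differences followed GC content (Spearman rho 0.53 over 11074 genes, which are not independent replicates) and length (-0.32).

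The largest group change was in ribosomal protein genes, whose products build the ribosome. All 40 tested rose (40 when adjusted over the list alone), with a median of 1.01, led by Rps4x (1.32), Rplp2 (1.29) and Rpl6 (1.27). Genes for nuclear-encoded subunits of complex I rose in 32 of 34 cases, with 1 fall and 1 not passing (32 and 1 over the list alone). Their median was 0.62, with examples in Ndufa11 (0.98), Ndufb10 (0.95) and Ndufs8 (0.94). Of the 38 subunits of complexes II to V, 33 rose, 1 fell and 4 did not pass (35 and 1 adjusted over the list alone). Their median was 0.55, led by the ATP synthase genes Atp5e (1.25) and Atp5d (1.10). Camera, which compares a list with all other genes, gave adjusted p = 1.99e-23, 1.97e-09 and 2.32e-10 for these 3 lists, and 0.033, 0.0263 and 0.033 with an estimated correlation. Random lists matched on expression, length and GC content had medians of 0.47 (95% range 0.38 to 0.6), 0.30 (0.13 to 0.44) and 0.24 (0.07 to 0.4). Ribosomal protein genes have many processed pseudogenes that share their fragments. Their share of all fragments was 3.74% ± 0.0929 in PCM and 6.22% ± 0.145 in SCM. In the same libraries Gm23935, a feature of 57 bp that resembles ribosomal RNA, rose from 21500 ± 5990 to 82800 ± 19600 FPKM. As a share of all fragments this was 0.13% in PCM and 0.41% in SCM. Lars2, the gene of the mitochondrial leucyl-tRNA synthetase, rose from 33.2 ± 8.59 to 126 ± 31.4. Its lowest and highest values among the 18 libraries, 24.6 and 163 FPKM, were those of the libraries with the least and the most Gm23935, so its values are uncertain as a measure of that gene.

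Genes of interferon signalling and of antigen display rose. Of 19 tested interferon-stimulated genes, 16 rose and 3 did not pass (16 over the list alone, median 0.78), including Isg15 (1.57), Bst2 (1.47) and Ifi27 (1.09). Untested members included Mx1, Oas2, Rsad2 and Psmb9, the last also in the next list. For MHC class I antigen presentation, 10 of 13 rose and 3 did not pass (10 over the list alone, median 0.72), including Psmb8 (1.05) and Psmb10 (0.87). H2-T23 rose by 1.08, but H2 genes share sequence with one another and are uncertain. Camera's adjusted p was 1.56e-05 and 0.00034, and 0.00406 and 0.0199 with an estimated correlation. In the same comparison Cd68, a marker of macrophages, rose by 1.28 (limma adjusted p = 4.55e-05) and Plvap, a marker of endothelium, by 0.65 (adjusted p = 0.000322).

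Genes of cholesterol synthesis, of the extracellular matrix and of late cell cycle phases also rose. In cholesterol synthesis 18 of 23 rose, 2 fell and 3 did not pass (18 and 2 over the list alone, median 0.48, adjusted p = 1.52e-05), with the mevalonate pathway genes Fdps (1.04) and Mvd (1.02). In G2 and M phase 26 of 34 rose, 4 fell and 4 did not pass (26 and 5 over the list alone, median 0.42, adjusted p = 1.52e-05), with cyclin B2 gene Ccnb2 (0.77) and the survivin gene Birc5 (0.75). Of 26 extracellular matrix genes 17 rose, 1 fell and 8 did not pass (17 and 1 over the list alone, median 0.36, adjusted p = 0.000261), with Fbln1 (1.21) and the collagen VI genes Col6a2 (1.14) and Col6a1 (1.13). Integrin and adhesion genes rose in 13 of 22 cases, with 3 falls and 6 not passing (13 and 3 over the list alone, median 0.28, adjusted p = 0.00543), among them the laminin receptor chain Itga7 (1.05). Glycolysis, with 23 identifiers for 22 listed genes because Aldoa has 2, gave 17 rises, 2 falls and 4 not passing (17 and 2 over the list alone, median 0.36, adjusted p = 0.000227), with Aldoc (1.06) and Tpi1 (0.96). All 5 tested fibroblast markers rose (5 over the list alone, median 0.68, adjusted p = 0.00879), among them C3 (0.82) and Gsn (0.68). Fap, Pdgfrb, Thy1 and other members were not tested.

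These 6 lists held with an estimated correlation, and 5 further lists did not. ATF4 targets, genes of the integrated stress response, rose in 17 of 27 cases with 6 falls and 4 not passing (17 and 6 over the list alone, median 0.36, adjusted p = 0.00543; adjusted p = 0.0689 with an estimated correlation), but the list's direction turned under quantile normalization (0.01). Gdf15 rose by 1.31 and the serine synthesis gene Phgdh by 0.95. ER stress genes rose in 11 of 18 cases with 4 falls and 3 not passing (11 and 4 over the list alone, median 0.34, adjusted p = 0.013; adjusted p = 0.0712 with an estimated correlation), with Manf at 0.80. NRF2 targets of the antioxidant response rose in 12 of 22 cases with 5 falls and 5 not passing (12 and 5 over the list alone, median 0.23, adjusted p = 0.0198; adjusted p = 0.0712 with an estimated correlation), with ferritin light chain gene Ftl1 at 1.15 and Gstm1 at 1.03. Epithelial genes rose in 8 of 14 cases with 1 fall, Tjp1 (-0.74), and 5 not passing (8 and 1 over the list alone, median 0.34, adjusted p = 0.0138; adjusted p = 0.0812 with an estimated correlation), with keratin gene Krt19 at 1.07. The list of immediate early and growth factor response genes fell. Of 29 genes 19 fell, 5 rose and 5 did not pass (19 and 5 over the list alone, median -0.38, adjusted p = 0.000998; adjusted p = 0.0992 with an estimated correlation), with the early response transcription factors Egr1 (-1.01) and Jun (-0.99) and with Myc (-0.85). Quantile normalization ended the calls of glycolysis, ER stress, epithelial genes, integrins and adhesion, and NRF2 targets. Scaling by library totals ended that of ER stress. Removal of the GC and length trend of each library gave medians of 0.41 for complex I, 0.34 for complexes II to V, 0.45 for MHC class I antigen presentation, 0.18 for glycolysis and 0.43 for fibroblast markers. They were 0.15 for ATF4 targets, 0.15 for NRF2 targets and 0.05 for epithelial genes, whose call ended.

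**Figure D2:**
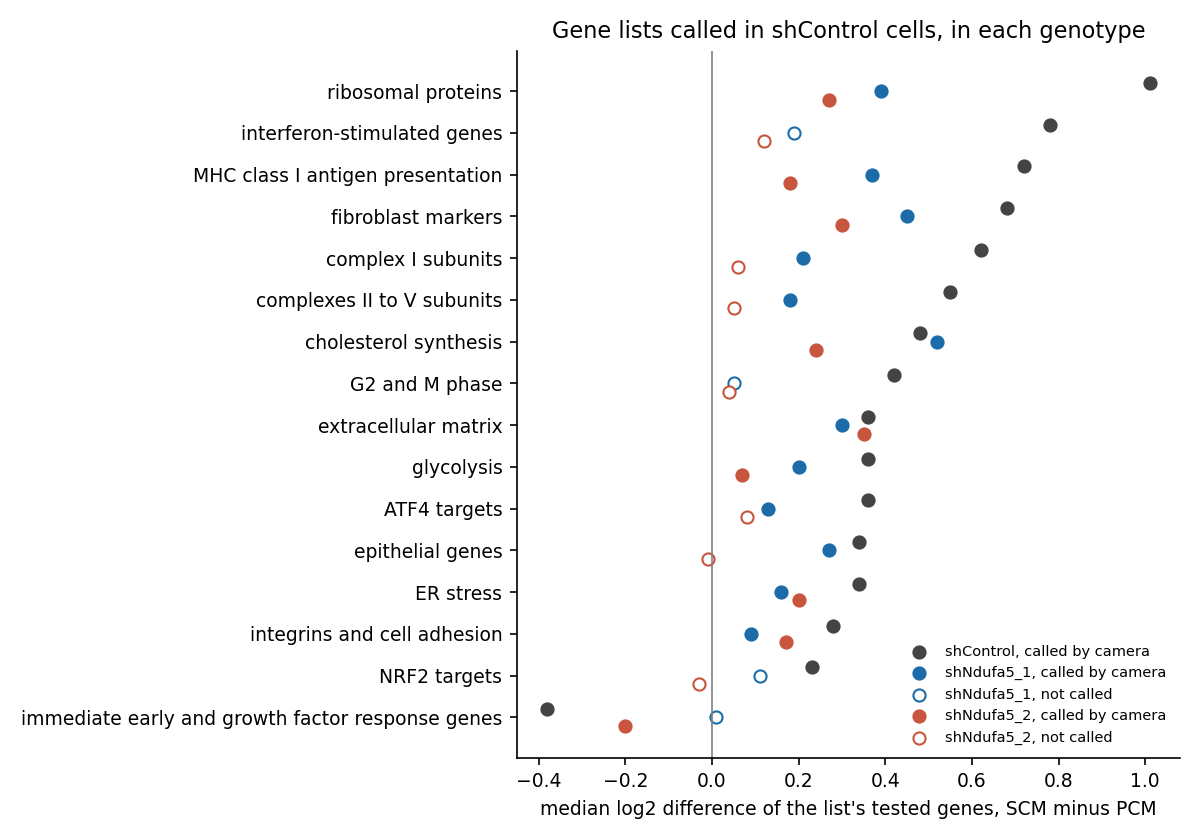
Median log2 difference between SCM and PCM (horizontal axis) of the tested members of the 16 lists called in shControl cells, with 1 point per genotype, filled where camera called the list. The medians in shControl run from -0.38 for immediate early genes to 1.01 for ribosomal proteins, and the direction of ATF4 targets in shControl turned under quantile normalization (0.01).

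The same change of medium altered fewer genes in the cells with a hairpin against Ndufa5. With shNdufa5_1, 4687 genes changed (2493 up, 2194 down, of which 26 and 7 at least 2-fold). In the libraries labelled shNdufa5_2, 2532 changed (1302 up, 1230 down, of which 12 and 5 at least 2-fold). Scaled by library totals, the split was 1996 up and 2691 down with shNdufa5_1 and 894 up and 2027 down in the libraries labelled shNdufa5_2. Cholesterol synthesis genes rose with shNdufa5_1 as in shControl, in 20 of 23 cases with 3 not passing (20 over the list alone, median 0.52, camera adjusted p = 5.06e-12). They rose in 11 of 23 cases with 12 not passing in the libraries labelled shNdufa5_2 (14 over the list alone, 0.24, adjusted p = 1.1e-06). Extracellular matrix genes rose in 19 of 26 cases with shNdufa5_1, with 1 fall (19 and 1 over the list alone, 0.30, adjusted p = 3.08e-06). They rose in 21 of 26 in the libraries labelled shNdufa5_2 (22 over the list alone, 0.35, adjusted p = 1.12e-15). Tested fibroblast markers rose in 5 of 5 with shNdufa5_1 (5 over the list alone, 0.45, adjusted p = 0.00183) and in 4 of 5 in the libraries labelled shNdufa5_2 (4 over the list alone, 0.30, adjusted p = 0.000469). Of the 13 genes of MHC class I antigen presentation, 9 rose with shNdufa5_1 (10 over the list alone, 0.37, adjusted p = 0.000329) and 6 in the libraries labelled shNdufa5_2 (7 over the list alone, 0.18, adjusted p = 0.000915). All of these calls held with an estimated correlation, and the median of MHC class I antigen presentation with shNdufa5_1 was 0.24 with the GC and length trend removed.

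Ribosomal protein genes rose in 39 of 40 cases with shNdufa5_1 (39 over the list alone, median 0.39, adjusted p = 5.69e-20; adjusted p = 0.0766 with an estimated correlation). They rose in 37 of 40 in the libraries labelled shNdufa5_2 (38 over the list alone, 0.27, adjusted p = 3.7e-22, and 0.0315 with an estimated correlation). Complex I subunits rose in 19 of 34 cases with 1 fall with shNdufa5_1 (20 and 1 over the list alone, 0.21, adjusted p = 0.000426; adjusted p = 0.139 with an estimated correlation). This median was 0.12 with the GC and length trend removed. Complex I subunits rose in 4 of 34 with 1 fall in the libraries labelled shNdufa5_2 (4 and 1 over the list alone, 0.06, adjusted p = 0.083). Interferon-stimulated genes were not called in either. Of 19 genes 6 rose and 3 fell with shNdufa5_1 (6 and 3 over the list alone, 0.19, adjusted p = 0.235). Of the 19, 4 rose in the libraries labelled shNdufa5_2 (4 over the list alone, 0.12, adjusted p = 0.133). In the libraries labelled shNdufa5_2, immediate early genes fell in 14 of 29 cases with 4 rises (14 and 4 over the list alone, -0.20, adjusted p = 5.78e-05; adjusted p = 0.0558 with an estimated correlation). ER stress genes rose there in 12 of 18 (13 over the list alone, 0.20, adjusted p = 1.05e-05, and 0.00703 with an estimated correlation). Of the 29 lists tested, camera called 13 with shNdufa5_1 and 15 in the libraries labelled shNdufa5_2, and 5 and 11 with an estimated correlation.

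Across all genes tested, the response with shNdufa5_1 followed that in shControl with a slope of 0.405 (Pearson r 0.608, same sign in 77.1%), and the response in the libraries labelled shNdufa5_2 with a slope of 0.194 (r 0.36, 62.8%). Over the 6863 genes called in shControl, a selected set whose slope is biased below 1, the slopes were 0.425 (r 0.744) and 0.202 (r 0.497). Of these genes 3617 and 1643 were called the same way against 144 and 352 the opposite way. In all 3 genotypes 716 genes rose and 419 fell, where independent lists would share 92.9 and 73.5. The 3 genotypes share no library here, and the correlations run across genes, which are not independent replicates. These differences followed GC content at rho 0.54 with shNdufa5_1 and 0.07 in the libraries labelled shNdufa5_2.

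**Figure D3:**
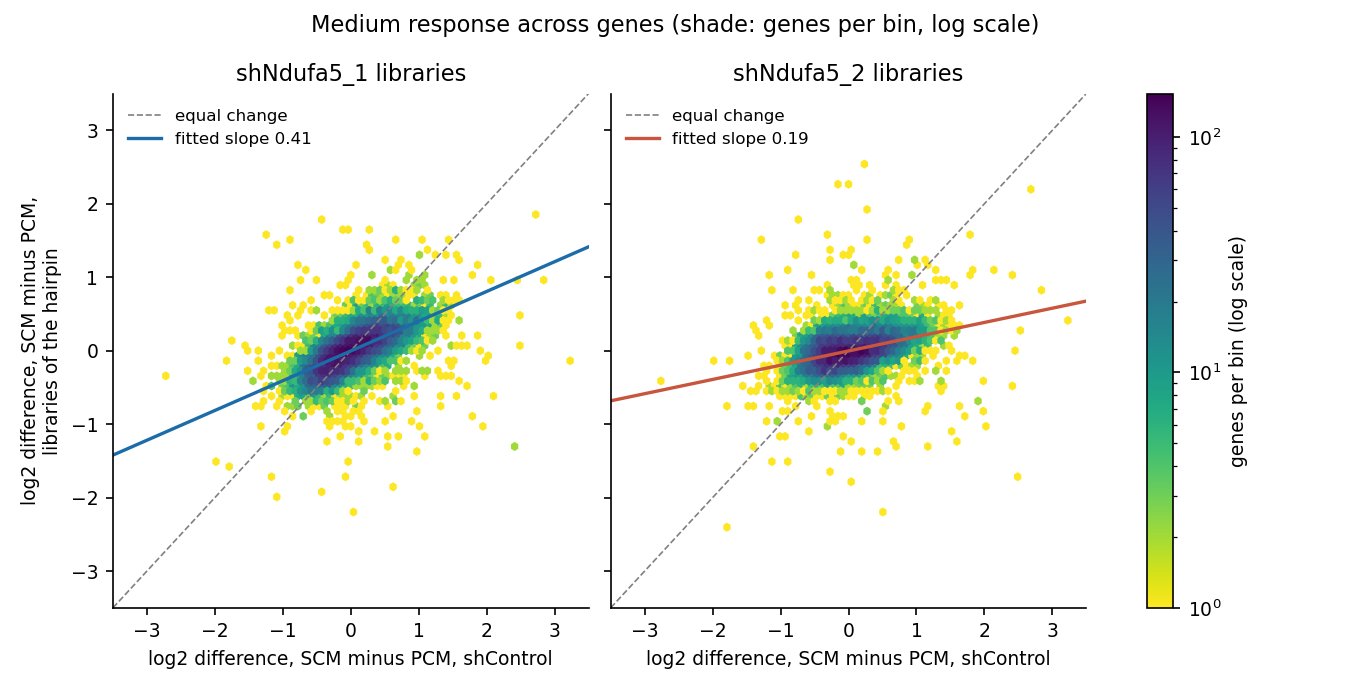
Log2 difference between SCM and PCM in the libraries of each hairpin (vertical axes) against that in shControl (horizontal axes) over 11084 genes, with shade for genes per bin, a dashed line for equal change and a solid fitted line. The fitted slopes are 0.405 for shNdufa5_1 and 0.194 for the libraries labelled shNdufa5_2.

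In PCM, the comparison of each hairpin with shControl asked what the hairpins did without the senescent secretome. With shNdufa5_1, mitotic and cholesterol synthesis genes rose, and genes of ER stress and of the inflammatory secretome fell. Of 34 G2 and M phase genes 33 rose and 1 did not pass (33 over the list alone, median 0.60, camera adjusted p = 2.26e-16), among them Ccnb2 (0.85) and the spindle assembly gene Tpx2 (0.68). Cholesterol synthesis genes rose in 20 of 23 cases with 3 not passing (20 over the list alone, 0.39, adjusted p = 2.64e-07), with Acat2 at 0.85. ER stress genes fell in 15 of 18 cases with 1 rise and 2 not passing (15 and 1 over the list alone, -0.35, adjusted p = 1.48e-07), with the chaperone gene Dnajb9 at -1.17. Genes of the inflammatory secretome and NF-kB targets fell in 13 of 22 tested with 1 rise and 8 not passing (13 and 1 over the list alone, -0.38, adjusted p = 0.000924), with Csf2 (-0.96) and Csf1 (-0.79). Il6, Il1b and Tnf were not tested.

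S phase genes rose in 16 of 31 cases with 2 falls and 13 not passing (17 and 2 over the list alone, 0.20, adjusted p = 0.0031), with the replication helicase gene Mcm2 at 0.76. NRF2 targets rose in 14 of 22 with 4 falls and 4 not passing (14 and 4 over the list alone, 0.34, adjusted p = 0.00232), with Prdx1 at 0.41. These 6 lists held with an estimated correlation. Ribosomal proteins fell in 28 of 40 cases with 2 rises (28 and 2 over the list alone, -0.29, adjusted p = 9.09e-07; adjusted p = 0.383 with an estimated correlation). Complex I subunits fell in 19 of 34 with 2 rises (19 and 2 over the list alone, -0.26, adjusted p = 0.0031; adjusted p = 0.317 with an estimated correlation). Complexes II to V fell in 19 of 38 with 4 rises (21 and 4 over the list alone, -0.15, adjusted p = 0.00555; adjusted p = 0.393 with an estimated correlation). These medians were -0.17, -0.17 and -0.09 with the GC and length trend removed, and the calls of complex I and of complexes II to V ended. In all, 5839 genes differed from shControl, 2839 up and 3000 down, of which 61 and 87 at least 2-fold (2755 up and 3144 down scaled by library totals). Camera called 11 of 29 lists, 6 with an estimated correlation.

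The libraries labelled shNdufa5_2 differed from shControl in PCM in 3947 genes, 2138 up and 1809 down, of which 26 and 8 at least 2-fold, although Ndufa5 did not pass the test there. Scaled by library totals the split was 1327 up and 2913 down. Interferon-stimulated genes were higher, in 15 of 19 cases with 4 not passing (16 over the list alone, median 0.58, adjusted p = 1.94e-08). Cd68 was higher too, by 1.48 (limma adjusted p = 4.15e-05), and so was Plvap, by 0.69 (adjusted p = 0.000498). Also higher were 39 of 40 ribosomal protein genes (39 over the list alone, 0.47, adjusted p = 1.99e-27) and 9 of 13 genes of MHC class I antigen presentation (9 over the list alone, 0.31, adjusted p = 0.000251). ER stress genes were higher in 12 of 18 cases and lower in 2 (12 and 2 over the list alone, 0.24, adjusted p = 0.00124), cholesterol synthesis genes in 12 of 23 and lower in 1 (12 and 1 over the list alone, 0.19, adjusted p = 0.00495). YAP and TEAD targets were lower in 9 of 15 and higher in 1 (9 and 1 over the list alone, -0.22, adjusted p = 0.000233), with the matricellular gene Cyr61 at -0.50. These 6 lists held with an estimated correlation. Complex I subunits were higher in 21 of 34 cases and lower in 1 (23 and 1 over the list alone, 0.27, adjusted p = 1.3e-06; adjusted p = 0.0606 with an estimated correlation). Complexes II to V were higher in 25 of 38 (27 over the list alone, 0.27, adjusted p = 2.74e-08; adjusted p = 0.0606 with an estimated correlation). The differences followed GC content at rho 0.46. With that trend and that of length removed, the median was 0.17 for complex I, 0.14 for complexes II to V and 0.17 for MHC class I antigen presentation. Gm23935 stood at 67800 ± 7240 FPKM against 21500 ± 5990 in shControl.

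Some genes moved the same way under both labels in PCM, fewer than went opposite ways, with the limit that Ndufa5 did not fall in the libraries labelled shNdufa5_2. Slpi rose by 0.89 with shNdufa5_1 and by 1.11 in the libraries labelled shNdufa5_2, the alarmin gene Il33 by 1.52 and 0.81, and Plau, which encodes urokinase, by 1.92 and 0.69. Other rises were the collagen V gene Col5a3 by 0.76 and 0.94, and Mcpt8 by 1.01 and 0.88. Gadd45g fell by 1.61 and by 0.81, Btg2 by 0.66 and by 0.72 and Csf2 by 0.96 and by 0.67. Also, the serpin gene Serpinb6b fell by 0.66 and by 1.08, the splicing regulator Tra2b by 0.74 and by 0.58, and the neuregulin gene Nrg1 by 0.86 and by 0.53. The same rule also named Lars2, Rnf5, Rpl37a, Gap43 and H1fx as rising by 0.64 to 1.55 and Zfp719, Taf1a, Itpripl2 and Map2k3os as falling by 0.55 to 0.88. Map2k3os lies antisense to Map2k3, so its fragments are uncertain, and so are those of Rpl37a because of its pseudogenes and the values of Lars2, which moved with Gm23935.

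In PCM 617 genes rose and 380 fell under both labels and 1500 went opposite ways. Independent lists would give 547.6, 489.6 and 1042, and 100 simulations of unchanged groups with the shared control libraries gave 0 shared calls on average. Such groups give almost no calls, so this 0, found for the overlaps in SCM and of the interaction as well, is no standard for an overlap. The differences of the 2 labels correlated across genes at r 0.022, where the shared controls alone gave 0.496, and their covariance of 0.0023 lay below all simulated ones (0.0091 to 0.0129, difference from the mean -0.0084). With the GC and length trend removed it was 0.0134, within the simulated range of 0.0089 to 0.0136. Part of any overlap may come from the shared control libraries, and 3 controls are too few to split. Scaled by library totals, 377 genes rose and 747 fell under both labels.

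In SCM, the same comparison asked how the hairpins altered cells exposed to the senescent secretome. Hspa1b, Hspb1, Cryab and Ccl5, which rose in SCM in shControl, were lower under both labels. Hspa1b stood at 19.8 ± 1.32 FPKM in shControl, at 1.46 ± 0.326 with shNdufa5_1 (log2 difference -3.08) and at 4.36 ± 0.554 in the libraries labelled shNdufa5_2 (-1.96). Hspb1 differed by -1.58 and -1.73. The lens and muscle small heat shock protein gene Cryab differed by -0.94 and -1.05, the chemokine gene Ccl5 by -2.60 and -0.98 and the nuclear RNA Malat1 by -1.01 and -0.79. Col5a3 was higher by 0.82 and 0.90, Plau by 1.74 and 0.72, the NAD-consuming ectoenzyme gene Cd38 by 1.03 and 0.69, the ceramidase gene Asah2 by 0.73 and 0.71, Galnt3 by 1.18 and 0.68, and the helicase gene Wrn by 0.63 and 0.61. The same rule also named Zfp469, Pbp2 and Serpinb2 (0.58 to 0.80) and the short Snora17 (1.16 and 1.03) among the rises. Among the falls it named Mir669n (-1.80 and -2.51) and the pseudogenes Rpl36-ps3, Rpl36-ps12, Rpl36-ps2 and Rps2-ps10 (-1.49 to -0.76). These pseudogenes share fragments with their parent genes.

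Among the lists, respiratory chain, interferon and ER stress genes were lower with shNdufa5_1 in SCM. Complex I subunits fell in 32 of 34 cases with 1 rise and 1 not passing (32 and 1 over the list alone, median -0.63, adjusted p = 1.5e-09), with Ndufs8 (-0.96) and Ndufa11 (-0.90). Complexes II to V fell in 32 of 38 with 1 rise and 5 not passing (32 and 1 over the list alone, -0.54, adjusted p = 1.14e-09), with Atp5e (-0.90) and Atp5d (-0.88). Interferon-stimulated genes fell in 17 of 19 cases with 1 rise, Ifit2 (0.39), and 1 not passing (18 and 1 over the list alone, -0.74, adjusted p = 1.2e-05), with Irf7 (-1.90) and Bst2 (-1.04). Cd68 differed by -1.50 (limma adjusted p = 8.48e-06) and Plvap by -0.35 (adjusted p = 0.0244). ER stress genes fell in 16 of 18 with 2 not passing (17 over the list alone, -0.54, adjusted p = 1.74e-08), with Manf at -1.65. Genes of MHC class I antigen presentation fell in 11 of 13 with 1 rise (11 and 1 over the list alone, -0.47, adjusted p = 0.000909), with a median of -0.28 when the GC and length trend was removed. Cholesterol synthesis genes rose in 18 of 23 cases with 1 fall (18 and 1 over the list alone, 0.44, adjusted p = 6.33e-06), with Stard4 at 0.66. G2 and M phase genes rose in 23 of 34 with 2 falls (23 and 2 over the list alone, 0.25, adjusted p = 5.39e-05), with Bub1 at 0.63. These 7 lists held with an estimated correlation. All 40 ribosomal protein genes fell (40 over the list alone, -0.80, adjusted p = 1.26e-20; adjusted p = 0.0528 with an estimated correlation). The inflammatory secretome list fell in 13 of 22 cases with 7 rises (13 and 7 over the list alone, -0.39, adjusted p = 0.0304; adjusted p = 0.159 with an estimated correlation), with Ccl5 (-2.60) and Lcn2 (-1.96). In all, 6631 genes differed, 3181 up and 3450 down, of which 79 and 225 at least 2-fold. Scaled by library totals, the median of all genes moved by 0.15 and 4842 were up and 2215 down.

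In the libraries labelled shNdufa5_2, 3758 genes differed from shControl in SCM, 1545 up and 2213 down, of which 8 and 18 at least 2-fold. The split turned to 2719 up and 1264 down with scaling by library totals and to 1750 up and 1273 down with quantile normalization. Complex I subunits were lower in 23 of 34 cases (26 over the list alone, median -0.28, adjusted p = 5.88e-08; adjusted p = 0.057 with an estimated correlation). Complexes II to V were lower in 24 of 38 (27 over the list alone, -0.25, adjusted p = 2.28e-09; adjusted p = 0.057 with an estimated correlation). Ribosomal proteins were lower in 34 of 40 (35 over the list alone, -0.25, adjusted p = 9.39e-13; adjusted p = 0.0868 with an estimated correlation), the last turning to 0.03 under quantile normalization and at -0.13 with the GC and length trend removed. G2 and M phase genes were lower in 20 of 34 cases and higher in 2 (21 and 2 over the list alone, -0.22, adjusted p = 2.93e-05; adjusted p = 0.057 with an estimated correlation). The inflammatory secretome list was lower in 14 of 22 (15 lower and 1 higher over the list alone, -0.25, adjusted p = 0.000374; adjusted p = 0.057 with an estimated correlation), with Cxcl10 (-0.75) and Lcn2 (-0.71). Interferon-stimulated genes were not called (2 of 19 higher and 3 lower, 1 and 3 over the list alone, -0.05, adjusted p = 0.883). Camera called 14 of 29 lists with the preset correlation, 0 with an estimated correlation at an adjusted p under 0.05 and 15 at an unadjusted p under 0.05. Fry, which asks only whether a list's genes move one way, called 22.

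In SCM 912 genes rose and 1469 fell under both labels and 440 went opposite ways, where independent lists would give 443.4, 688.8 and 1116. Part of the excess of shared calls may come from the shared control libraries. The correlation across genes was 0.48, the value from shared controls alone 0.502, and the covariance exceeded the simulated one by 0.0455, or by 0.0256 with the GC and length trend removed. Scaled by library totals 1969 rose and 699 fell under both labels, and with the GC and length trend removed 581 rose and 878 fell. With only the groups compared in the fit 489 rose, and under quantile normalization 664 fell.

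The differences from shControl in PCM and in SCM share no library. For shNdufa5_1 they correlated across genes at r 0.65 (at most 0.105 in 100 simulations without effects). The count was 2009 genes up and 2149 down in both media and 271 opposite, against 814.8 and 933.8 for independent lists. For the libraries labelled shNdufa5_2 they correlated at r -0.24, below all 100 simulations (-0.092 to 0.099). The count was 178 up and 220 down in both media and 1504 opposite, against 298 and 361.2. With the GC and length trends removed the values were 0.63 and -0.06.

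The interaction compared the response to SCM under the hairpin labels with that in shControl. The responses of Hspa1b and of interferon-stimulated, respiratory chain and ribosomal protein genes were lower under the hairpin labels than in shControl, and those of several genes that fell in shControl were higher. A higher response means a more positive log2 difference between SCM and PCM, so for a gene that fell in shControl it can be a smaller fall. A lower response can come from a higher level in PCM as well as from a lower level in SCM. With the GC and length trend removed, the shNdufa5_2 label gave interferon-stimulated medians of 0.52 against shControl in PCM and -0.01 in SCM. Ribosomal proteins gave 0.37 and -0.13 there and complex I 0.17 and -0.19. With shNdufa5_1 these lists gave -0.04 and -0.64, -0.17 and -0.66, and -0.17 and -0.45 in the same order. Averaged over both labels, the response of Hspa1b was lower by 3.06 ± 0.20 on the log2 scale (difference -3.06), that of Hspb1 by 2.14 ± 0.23 (-2.14), that of Irf7 by 1.84 ± 0.12 (-1.84) and that of Ccl5 by 1.74 ± 0.21 (-1.74). The responses of Gadd45g (1.10 ± 0.08), Filip1l (1.03 ± 0.09), Csf2 (1.02 ± 0.16), Btg2 (0.99 ± 0.18), Srsf3 (0.95 ± 0.05), the translation initiation factor gene Eif5 (0.94 ± 0.05) and the ubiquitin ligase adaptor gene Kctd11 (0.97 ± 0.08) were higher, all of them genes with a fall in SCM in shControl. The difference of Csf2 was 1.74 for shNdufa5_1 (adjusted p = 6.86e-06) and 0.29 in the libraries labelled shNdufa5_2 (adjusted p = 0.231), so its average rests on shNdufa5_1. The medium itself gave 0.52 for Csf2 with shNdufa5_1 (adjusted p = 0.00539) and -0.93 in the libraries labelled shNdufa5_2 (adjusted p = 0.000156). For Hspa1b it gave -0.11 (adjusted p = 0.609) and 0.41 (adjusted p = 0.0903). The same rule named Lars2 (-2.25), uncertain because it moved with Gm23935, Rn7sk (-2.48), Snord55 (-1.65), Snord7 (-2.07), Mir6955 (-3.28) and Mir194-1 (-3.09) among the lower and Mir1957a (1.91), mt-Ts2 (1.25) and mt-Tr (0.93) among the higher. Apart from Lars2 and Rn7sk these are under 300 bp, and with no filter on low values the adjusted p of Rn7sk, Snord55, Snord7, Mir194-1, Mir1957a, mt-Ts2 and mt-Tr no longer passed.

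Counted where it passed the test, the interaction was negative in 38 of the 40 ribosomal protein genes (39 over the list alone, median -0.67, adjusted p = 1.9e-27), with Rplp1 at -0.91 and Rpl6 at -0.87. Complex I subunits had a negative interaction in 30 of 34 and a positive one in 1 (31 and 1 over the list alone, -0.46, adjusted p = 1.12e-10), with Ndufa11 (-0.78) and Ndufb10 (-0.73). Complexes II to V had a negative interaction in 31 of 38 (32 over the list alone, -0.47, adjusted p = 1.35e-12), with Atp5e (-0.94) and Atp5d (-0.87). Interferon-stimulated genes had a negative interaction in 14 of 19 cases (15 over the list alone, -0.55, adjusted p = 1.32e-06), with Isg15 at -1.59. The response of Cd68 differed by -1.11 (limma adjusted p = 0.00213) and that of Plvap by -0.07 (adjusted p = 0.758). G2 and M phase genes had a negative interaction in 22 of 34 and a positive one in 1 (22 and 1 over the list alone, -0.33, adjusted p = 6.37e-08), with Birc5 (-0.74) and Cenpa (-0.57). NRF2 targets had a negative interaction in 11 of 22 and a positive one in 2 (11 and 2 over the list alone, -0.24, adjusted p = 0.0026), with the ferritin genes Ftl1 (-1.03) and Fth1 (-0.87). MHC class I antigen presentation genes had a negative interaction in 9 of 13 (10 over the list alone, -0.39, adjusted p = 0.00473), with Psmb10 (-0.74) and Psme1 (-0.52). These 7 lists held with an estimated correlation, and quantile normalization ended the calls of NRF2 targets and MHC class I antigen presentation. Removal of the GC and length trend gave medians of -0.29 for complex I, -0.30 for complexes II to V and -0.19 for MHC class I antigen presentation.

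In the list of immediate early genes, which fell in SCM in shControl, the interaction was positive in 16 of 29 cases and negative in 6 (17 and 6 over the list alone, 0.28, adjusted p = 0.00473; adjusted p = 0.171 with an estimated correlation), with Egr1 (0.92) and Egr2 (0.76). Glycolysis genes had a negative interaction in 15 of 23 and a positive one in 3 (15 and 3 over the list alone, -0.22, adjusted p = 0.00473; adjusted p = 0.0621 with an estimated correlation), a direction that turned under quantile normalization (0.03), with Tpi1 at -0.69 and Aldoa, which has 2 identifiers and several pseudogenes, at -0.64 and -0.56. ATF4 targets had a negative interaction in 17 of 27 and a positive one in 4 (17 and 4 over the list alone, -0.17, adjusted p = 0.00473; adjusted p = 0.0829 with an estimated correlation), a direction that turned under quantile normalization (0.01), with a median of 0.02 under scaling by library totals, where that of all genes was 0.16, and with Gdf15 (-1.02) and Phgdh (-0.70). The median of glycolysis was -0.14 and that of ATF4 targets, whose call ended, -0.07 when the GC and length trend was removed. By single label, immediate early genes gave 0.28 and 0.13 (not called, adjusted p = 0.105) for shNdufa5_1 and the libraries labelled shNdufa5_2. In the same order glycolysis gave -0.10 (not called, adjusted p = 0.166) and -0.34, and ATF4 targets -0.10 (not called, adjusted p = 0.0741) and -0.30.

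The averaged interaction passed in 4280 genes, 1902 higher and 2378 lower, of which 12 and 60 by at least 2-fold. The split turned to 4081 higher and 1202 lower with scaling by library totals, which moved the median of all genes by 0.16, and to 2019 and 1444 with quantile normalization. The interaction passed in 2900 genes for shNdufa5_1 (1186 higher, 1714 lower) and in 4768 for the libraries labelled shNdufa5_2 (2096 higher, 2672 lower), with 3317 and 769 and with 3559 and 1412 under library totals and 1424 and 988 and 2246 and 1729 under quantile normalization. With the GC and length trend removed, 2711 genes passed for shNdufa5_1 and 2951 for the libraries labelled shNdufa5_2. Both shared 674 higher and 1446 lower genes and 66 opposite ones, against 224.3, 413.2 and 610 for independent lists. The shared genes numbered 2162 higher and 651 lower under library totals, and quantile normalization left 717 lower. Part of the excess of shared calls may come from the 6 shared control libraries. The correlation was 0.67 against 0.494 from shared controls, and the covariance exceeded the simulated one by 0.0773. In the libraries of every group but shControl in PCM, Gm23935 stood above the 21500 ± 5990 FPKM of that group (57900 ± 36800 with shNdufa5_1 and 67800 ± 7240 under shNdufa5_2 in PCM, 82800 ± 19600, 48200 ± 16300 and 39200 ± 11300 for shControl, shNdufa5_1 and shNdufa5_2 in SCM). The differences of the interaction followed GC content at rho -0.45.

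**Figure D4:**
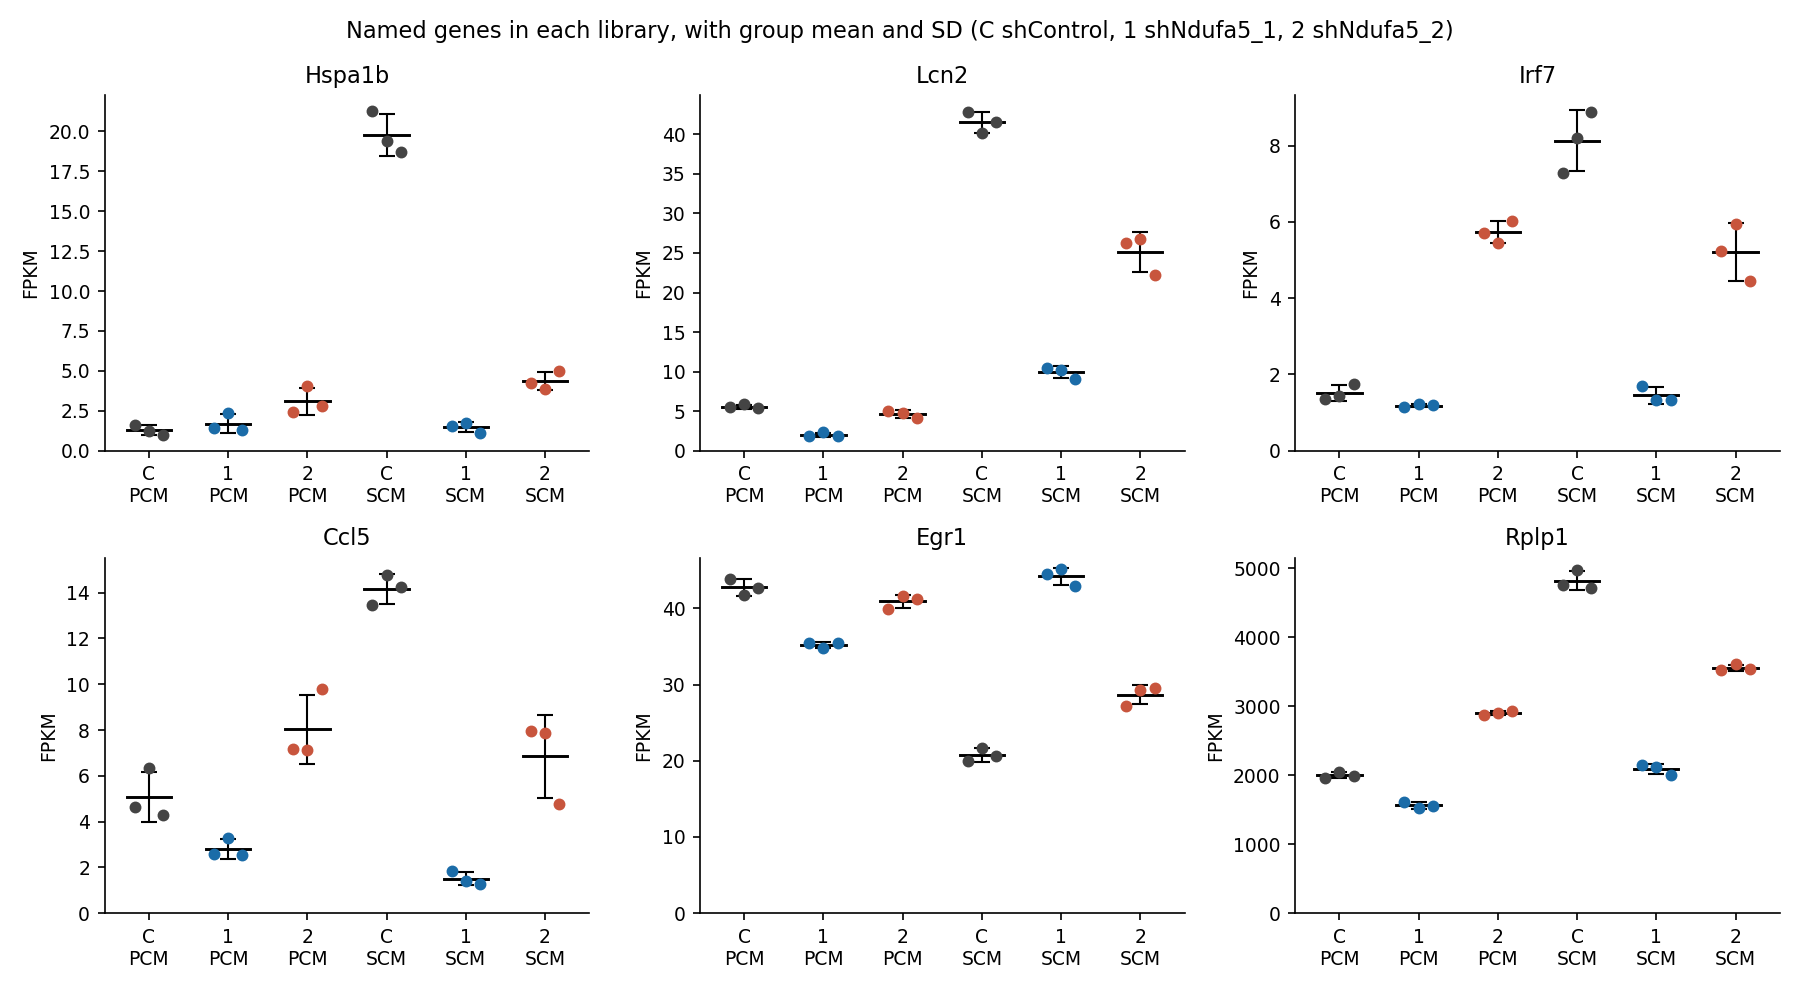
FPKM of Hspa1b, Lcn2, Irf7, Ccl5, Egr1 and Rplp1 in each library by genotype and medium, with points for libraries, lines for group means and error bars for the SD of 3 libraries. Hspa1b reaches 19.8 ± 1.32 (SD, n = 3) in shControl in SCM and stays at 1.46 ± 0.326 with shNdufa5_1 and 4.36 ± 0.554 in the libraries labelled shNdufa5_2, and the difference of Rplp1 between shControl and the libraries labelled shNdufa5_2 in SCM vanished (0) under quantile normalization.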

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

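The lists and the comparison of the responses were planned, and the tests of a common loss of Ndufa5 function and of the GC and length trend were chosen after results had been seen. The results in this part are those in which the response to SCM under a hairpin label differed from that in shControl by the limma test of the difference itself. Ndufa5 did not fall in PCM in the libraries labelled shNdufa5_2, which limits each direction drawn from them.

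The response differed in 2900 genes for shNdufa5_1, in 4768 for the libraries labelled shNdufa5_2 and in 4280 for their average. With the GC and length trend removed the counts were 2711, 2951 and 3140. The response of ribosomal protein genes was lower by medians of -0.58, -0.71 and -0.67 in that order, that of complex I subunits by -0.40, -0.53 and -0.46, complexes II to V by -0.41, -0.52 and -0.47, interferon-stimulated genes by -0.49, -0.59 and -0.55, and G2 and M phase genes by -0.29, -0.37 and -0.33. These 5 lists held in each of the 3 tests with an estimated correlation. Cd68, the only member of the immune list that was tested, gave -1.10, -1.12 and -1.11 (limma adjusted p = 0.00914, 0.00461 and 0.00213). MHC class I antigen presentation gave -0.34 (adjusted p = 0.0848 with an estimated correlation), -0.41 and -0.39. NRF2 targets gave -0.19 (adjusted p = 0.0732 with an estimated correlation), where the median was 0 under scaling by library totals and that of all genes 0.16, and -0.37 and -0.24.

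For shNdufa5_1 alone, the 13 genes of the mitochondrial genome list (12 tested) gave -0.31 (adjusted p = 0.357 with an estimated correlation), which turned to 0.16 under quantile normalization. ER stress genes gave -0.18 (adjusted p = 0.145 with an estimated correlation), which turned to 0.04 under quantile normalization, and lay at 0.02 under library totals, below the 0.16 of all genes. Immediate early genes gave 0.28 (adjusted p = 0.107 with an estimated correlation) for shNdufa5_1 and 0.28 for the average (adjusted p = 0.171 with an estimated correlation). In the libraries labelled shNdufa5_2, glycolysis gave -0.34 and cholesterol synthesis -0.32, both held with an estimated correlation. The TCA cycle gave -0.18 there (adjusted p = 0.102 with an estimated correlation), S phase -0.18 (adjusted p = 0.0974 with an estimated correlation), and epithelial genes -0.22 (adjusted p = 0.112 with an estimated correlation). ATF4 targets gave -0.30 (adjusted p = 0.0502 with an estimated correlation), which turned to 0.07 under quantile normalization. For the average, glycolysis gave -0.22 (adjusted p = 0.0621 with an estimated correlation) and turned to 0.03 under quantile normalization, and ATF4 targets gave -0.17 (adjusted p = 0.0829 with an estimated correlation) and turned to 0.01 under it, and lay at 0.02 under library totals, below the 0.16 of all genes.

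Some of these medians moved by over 1.5 times or lost their call with the GC and length trend removed. For shNdufa5_1 complex I gave -0.24, and MHC class I antigen presentation -0.23 with its call lost. Under the label shNdufa5_2 complex I gave -0.33, complexes II to V -0.34, glycolysis -0.15, MHC class I antigen presentation -0.19 and NRF2 targets -0.18, and the calls of ATF4 targets (-0.03) and epithelial genes (-0.05) were lost. For the average, complex I gave -0.29, complexes II to V -0.30, glycolysis -0.14 and MHC class I antigen presentation -0.19, and the call of ATF4 targets (-0.07) was lost.

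Among single genes, the averaged response was lower for Mir6955 (-3.28), Mir194-1 (-3.09), Hspa1b (-3.06), Rn7sk (-2.48), Lars2 (-2.25), Hspb1 (-2.14), Snord7 (-2.07), Irf7 (-1.84), Ccl5 (-1.74) and Snord55 (-1.65). It was higher for Mir1957a (1.91), mt-Ts2 (1.25), Gadd45g (1.10), Filip1l (1.03), Csf2 (1.02, with 0.29 and adjusted p = 0.231 in the libraries labelled shNdufa5_2), Btg2 (0.99), Kctd11 (0.97), Srsf3 (0.95), Eif5 (0.94) and mt-Tr (0.93). Lars2 moved with Gm23935, and with no filter on low values Rn7sk, Snord55, Snord7, Mir194-1, Mir1957a, mt-Ts2 and mt-Tr lost their call. In the respiratory lists Ndufa11 gave -0.78, Ndufb10 -0.73, Atp5e -0.94 and Atp5d -0.87, and in glycolysis Tpi1 gave -0.69 and Aldoa -0.64. Gdf15 gave -1.02 and Phgdh -0.70, Isg15 -1.59, Psmb10 -0.74 and Psme1 -0.52. Birc5 and Cenpa of the mitotic list gave -0.74 and -0.57, the ferritin genes Ftl1 and Fth1 -1.03 and -0.87, Egr1 and Egr2 0.92 and 0.76, and Rplp1 and Rpl6 -0.91 and -0.87.

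Other assignments of the medium labels within each genotype were drawn 100 times, the real one included. For the libraries labelled shNdufa5_2, 1 of the 100 gave as many genes (4768, highest other 3945). A whole swap in both shControl and these libraries, with shNdufa5_1 kept, only turns the sign and gives the same count. The share thus depends on which assignments were drawn. For shNdufa5_1 it was 8 of 100 (2900, highest other 4687) and for the average 8 of 100 (4280, highest other 5261). The other 7 in each case kept or swapped a genotype whole, which can turn the medium's effect into an interaction. In the 80 that mixed every genotype the highest counts by limma were 1, 0 and 0 for shNdufa5_1, shNdufa5_2 and the average. Mixing adds the medium's effect to the spread within groups, so none of these shares or counts can decide on chance. For each of the 7 pairwise comparisons, 1 of 10 splits of the 6 libraries, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real count and the highest other were 6863 and 0, 4687 and 1, and 2532 and 1 for SCM against PCM in shControl, shNdufa5_1 and the libraries labelled shNdufa5_2, 5839 and 0 and 3947 and 1 for the hairpins in PCM, and 6631 and 1 and 3758 and 2 for those in SCM.

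Ribosomal protein and respiratory chain genes rose in SCM in shControl and had a lower response under both hairpin labels. A trend with expression level, length and GC content does not account for all of it, since the medians of the averaged interaction (-0.67, -0.46 and -0.47) lay below the lowest 2.5% of 10000 matched random lists (-0.47, -0.35 and -0.33 for ribosomal proteins, complex I and complexes II to V). The scaling of the deposited values does not account for the rise in SCM, since the ribosomal protein median in shControl stayed at 0.76 under library totals. Carry-over of ribosomal RNA that varied between libraries stays open. Within groups, Gm23935 and the mean of ribosomal protein genes correlated at r = -0.26 (permutation p = 0.463, r = -0.04 without the 2 farthest libraries, 18 libraries). In PCM, ribosomal proteins fell with shNdufa5_1 and rose under shNdufa5_2, both with more Gm23935 than shControl. A hairpin-dependent response of these genes to the secretome is a hypothesis, with carry-over open as a mark of another difference between the libraries.

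The libraries labelled shNdufa5_2 differed from shControl in 3947 genes in PCM although Ndufa5 did not fall there. A swap of the medium labels within these libraries is argued against by the medium response of 4687 genes called in shNdufa5_1, whose median in the same direction was above 0 (0.08, SE 0.007 between libraries), and a GC and length trend as the whole cause by the 2882 genes that still differed with the trend removed. A loss of Ndufa5 function common to both hairpins stays open: the covariance of their differences in PCM, 0.0023, was -0.0084 relative to the simulated mean and below all 100 simulations (0.0091 to 0.0129), but with the trend removed it was 0.0134, within the simulated range of 0.0089 to 0.0136. Whether the libraries in PCM are shControl libraries also stays open. Their differences from shControl in PCM and SCM correlated at r = -0.24, or -0.06 with the trend removed, so r cannot decide. These libraries differed in fewer genes, 2532, from their own label in SCM. Identity would leave the 3947 genes to a separate culture or preparation that the labels do not give. An effect of the hairpin outside Ndufa5 was not tested.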

How the results depend on the processing

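Scaling by library totals, voom, the limit on gene length and removal of the GC and length trend were chosen after seeing the data, and the other alternatives were planned. Counts of changed genes stayed within 1.5 times the reported ones under 119 of 130 tests of an alternative, and in all 180 fits that left out 1 library. The exceptions were an absolute log2 difference of at least 1, which by construction left 291, 33 and 17 genes for SCM against PCM in shControl, shNdufa5_1 and the libraries labelled shNdufa5_2, 148 and 34 for the hairpins in PCM, 304 and 26 in SCM, and 64, 120 and 72 for the interaction of each hairpin and of both, and removal of the GC and length trend, which left 2951 for the interaction of the libraries labelled shNdufa5_2. Median-ratio scaling had the factor 1.008 in every library. It moved 4 of the 10 counts of changed genes by 1 or 2 and ended the call of 1 named gene, Rrm2b with shNdufa5_1 in SCM, so its results, counted here as kept or lost, say nothing on stability. The replicate numbers did not pair the libraries: residuals of libraries with the same number correlated at a mean r of 0.004 (-0.093 to 0.065 over 45 pairs) and of different numbers at -0.002 (90 pairs), and 1 of 18 libraries correlated best with its own number. With a replicate block 6810 genes changed for SCM against PCM in shControl and 4176 for the averaged interaction, and 1 called list lost its call. The fall of Ndufa5 in SCM in the libraries labelled shNdufa5_2 was -0.31 with the GC and length trend removed (adjusted p = 0.0608), and ran from -0.56 to -0.33 when 1 library was left out, with the call lost in 2 of those fits; the other tests of Ndufa5 kept their call or lack of one.

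For the lists, fry, which does not compare a list with other genes, called 26, 24 and 24 for SCM against PCM in shControl, shNdufa5_1 and the libraries labelled shNdufa5_2, 25 and 21 for the hairpins in PCM, 25 and 22 in SCM and 25, 21 and 24 for the interactions. An estimated correlation left 5 for SCM against PCM in shNdufa5_1, 6 and 6 for the hairpins in PCM, 0 in SCM for the libraries labelled shNdufa5_2 (15 at an unadjusted p under 0.05, 22 by fry) and 5 for the interaction of shNdufa5_1. Quantile normalization gave 8 for SCM against PCM in shNdufa5_1, and 16 and 6 for shNdufa5_1 and the libraries labelled shNdufa5_2 against shControl in SCM, and no filter gave 16 for the averaged interaction. Under quantile normalization 8 medians reversed: ATF4 targets 0.01 (SCM in shControl), 0.07 and 0.01 (interaction of the libraries labelled shNdufa5_2 and of both), the mitochondrial genome 0 (SCM in the libraries labelled shNdufa5_2) and 0.16 (interaction of shNdufa5_1), ribosomal proteins 0.03 (libraries labelled shNdufa5_2 in SCM), ER stress 0.04 (interaction of shNdufa5_1) and glycolysis 0.03 (interaction of both). The cause was not tested. Another 135 tests of called lists lost the call in the same direction against 1574 that kept it, and 25 against 2189 with 1 library left out.

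The slope of the response on that of shControl over all genes tested was 0.36 with a pseudocount of 0.1, 0.35 without a filter and 0.33 with the GC and length trend removed for shNdufa5_1, and for the libraries labelled shNdufa5_2 0.17, 0.17 and 0.26, with 0.22 at a mean FPKM of at least 5 and 0.21 under quantile normalization. Over genes called in shControl it was 0.35 for shNdufa5_1 with the trend removed and, for the libraries labelled shNdufa5_2, 0.28 with the trend removed and 0.23 under quantile normalization. Genes shared by both labels numbered 377 up and 747 down in PCM, 1969 and 699 in SCM and 2162 and 651 in the interaction under library totals, and 2 and 0, 2 and 7, and 2 and 30 by limma at an absolute log2 difference of at least 1. In SCM 581 rose and 878 fell with the trend removed, 489 rose with only the groups compared and 664 fell under quantile normalization, which left 717 lower in the interaction. The cause was not tested.

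Of the named genes, 8059 tests kept their result, 322 lost a call, 12 gained one and 53 reversed, and with 1 library left out 12543 kept it, 306 lost it and 3 gained one. Under quantile normalization the reversals for SCM against PCM in shControl were mt-Co1 (-0.16), mt-Nd4 (-0.48), mt-Nd2 (-0.45), Lonp1 (-0.06), Krt18 (-0.21) and Axl (-0.22). For the libraries labelled shNdufa5_2 in PCM they were mt-Nd4 (-0.15), mt-Nd1 (-0.45), Shmt2 (0), H2-D1 (-0.04), Spp1 (-0.25), Krt18 (-0.18), Txn1 (-0.03) and Rpl4 (-0.17), and in SCM mt-Nd2 (0.04), H2-D1 (0.02), Fth1 (0.05), Taldo1 (0.02), Srebf2 (0.06) and Rplp1 (0). For shNdufa5_1 in SCM they were mt-Nd2 (0.33), Pgk1 (0.35), Idh2 (0.09), Phgdh (0.07), Psat1 (0.10), Uhrf1 (0.11), Ube2c (0.18), Krt19 (0.34), Tkt (0), Srebf2 (0.16) and Ly6c1 (0.23), and for the averaged interaction mt-Nd2 (0.20), mt-Co1 (0.16), mt-Nd4 (0.31), Calr (0.04), B2m (0.04), Vim (0.06), Axl (0.35) and P4ha1 (0.04). With the GC and length trend removed, Abcg2 (0.06, SCM in shControl), Krt18 (-0.01, libraries labelled shNdufa5_2 in PCM), Dtl (-0.02, the same label in SCM) and Idh2 (0.08), Rrm2b (-0.05), Ube2c (0.11) and Krt19 (0.04, all shNdufa5_1 in SCM) reversed. Scaling by library totals reversed Idh2 (0.03), Uhrf1 (0.06), Ube2c (0.05) and Srebf2 (0.04) for shNdufa5_1 in SCM and Axl (0.10) and P4ha1 (0.02) in the averaged interaction, where it moved the median of all genes by 0.15 and 0.16. The cause was not tested. Depth limits short features and genes near an FPKM of 1.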

Other observations

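The list of heat shock genes and the values of Gm23935 and Rn7sk per library were chosen after results had been seen. Several gene groups were not called by camera for SCM against PCM in shControl, although many members changed. Of 22 tested genes of the inflammatory secretome and NF-kB targets, 14 rose, 7 fell and 1 did not pass (14 and 7 over the list alone, median 0.28, adjusted p = 0.197), with Ccl5 (1.33) and Cxcl2 (1.16) up and Csf2 (-1.22) down. Il6, Il1a, Il1b, Tnf and other members were not tested. Of 20 p53 targets 7 rose, 7 fell and 6 did not pass (7 and 7 over the list alone; median 0.03, mean -0.11, tested as down, adjusted p = 0.702), with Plk2 (-0.60) and Mdm2 (-0.52), the gene of the ligase that degrades p53, down. Of 31 S phase genes 12 rose, 10 fell and 9 did not pass (13 and 10 over the list alone; 0.09, adjusted p = 0.702), with the replication genes Gins2 (0.48) up and Pola1 (-0.56) down. Of 16 hypoxia and HIF targets 9 rose, 1 fell and 6 did not pass (9 and 1 over the list alone; 0.14, adjusted p = 0.171), with the collagen hydroxylase gene P4ha1 at 0.67. TGF-beta targets split into 7 rises and 9 falls with 4 not passing of 20 (8 and 9 over the list alone; median -0.02, mean 0.01, adjusted p = 0.773), with Tgfb1 (1.06) and Id1 (0.78) up and Bmp4 (-0.62) down. YAP and TEAD targets gave 4 rises and 5 falls with 6 not passing of 15 (4 and 5 over the list alone; -0.10, adjusted p = 0.545), with Ajuba at -0.33.

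In the mitochondrion, the TCA cycle gave 10 rises and 4 falls with 4 not passing of 18 (10 and 4 over the list alone; median 0.20, adjusted p = 0.172), with Mdh2 (0.74) up and Dld (-0.60) down. Transcripts of the mitochondrial genome rose in 5 of 12 cases, fell in 1 and did not pass in 6 (5 and 1 over the list alone; 0.16, adjusted p = 0.172), with mt-Nd3 at -0.53 and mt-Co1 at 0.68, a direction that turned under quantile normalization (-0.16). Complex I assembly factors gave 5 rises and 5 falls with 7 not passing of 17 (4 and 5 over the list alone; -0.08, adjusted p = 0.618), with Ndufaf8 (0.73) up and Lyrm2 (-0.63) down, and mitochondrial chaperones and proteases 7 and 3 with 5 not passing of 15 (7 and 3 over the list alone; 0.09, adjusted p = 0.43), with the protease subunits Clpp (0.49) up and Clpx (-0.53) down. Of 18 mesenchymal genes 8 rose, 3 fell and 7 did not pass (8 and 3 over the list alone; 0.15, adjusted p = 0.189), with S100a4 (0.86) up and the transcription factor gene Snai2 (-0.89) down. Stem cell-associated genes gave 2 rises and 5 falls with 3 not passing of 10 (2 and 5 over the list alone; -0.16, adjusted p = 0.209), with Bmi1 at -0.61. Replication-dependent histones, whose near-identical copies make them uncertain, gave 1 rise and 2 falls with 3 not passing of 6 (1 and 2 over the list alone; median 0.13, tested as down, adjusted p = 0.773), with Hist1h1c at -0.60. Among markers of other cell types with too few tested members for a list test, Cd68 of the immune list rose by 1.28, Plvap of the endothelial list by 0.65 and Msln of the mesothelial list by 0.55; no other member of the immune, endothelial or mesothelial lists had a mean FPKM of at least 1.

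Hspa1b, Hspb1 and Cryab rose in SCM in shControl, which may reflect a heat shock factor programme, a hypothesis formed on these data. In a list of 18 other heat shock genes written before the test, 16 were tested, of which 9 rose and 6 fell in that comparison, with a median of 0.23 (camera p = 0.17, adjusted p = 0.28, and p = 0.27, adjusted p = 0.41, with an estimated correlation), so the hypothesis stays open. Hspa8 (1.15), Hsp90ab1 (0.82) and Serpinh1 (0.63) rose and Chordc1 (-0.55) fell. Counted where it passed, the averaged interaction was positive in 4 and negative in 9 (median -0.34, camera p = 0.022, adjusted p = 0.055 over the 10 comparisons, and p = 0.078, adjusted p = 0.2, with an estimated correlation). The interaction was negative in 9 for shNdufa5_1 (-0.29, p = 0.00014, adjusted p = 0.0014, and p = 0.0074, adjusted p = 0.06, with an estimated correlation), and for the libraries labelled shNdufa5_2 positive in 6 and negative in 9 (-0.28, p = 0.27, adjusted p = 0.3, and p = 0.37, adjusted p = 0.41, with an estimated correlation). With shNdufa5_1 in PCM 10 of these genes were higher than in shControl and 2 lower (0.29, p = 0.00094, adjusted p = 0.004, and p = 0.016, adjusted p = 0.06, with an estimated correlation), and in SCM 7 were higher and 7 lower (-0.01, p = 0.82, adjusted p = 0.82, and p = 0.85, adjusted p = 0.85, with an estimated correlation). In the libraries labelled shNdufa5_2, 4 were higher and 7 lower in PCM (-0.08, p = 0.26, adjusted p = 0.3, and p = 0.37, adjusted p = 0.41, with an estimated correlation), and 2 higher and 10 lower in SCM (-0.22, p = 0.0012, adjusted p = 0.004, and p = 0.018, adjusted p = 0.06, with an estimated correlation).

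The shNdufa5_1 library in PCM with replicate number 2 held Gm23935 at 99870 FPKM against 42110 and 31610 in the other replicates, and Rn7sk at 143.5 against 23.35 and 15.11. The first and second principal components of the 18 libraries took 42% and 16.7% of the variance. No pair of replicates agreed within sampling noise: the chi-square per degree of freedom over recovered fragments was 3.37 to 11.12 over the 18 pairs within groups. The libraries labelled shNdufa5_2 in PCM differed from shControl in SCM in 4453 genes.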
